A study of Mus musculus with 20 samples.

How the data were processed

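RNA was measured by sequencing in 2 populations sorted from mouse bone marrow by flow cytometry, long-term haematopoietic stem cells (LT-HSC) and multipotent progenitors (MPP). Per the labels, the animals were untreated, 8 to 12 weeks old, and either wild type (WT, C57BL/6) or knocked out for Ahr, the gene of the aryl hydrocarbon receptor (Ahr-KO). Each of the 4 groups holds 5 libraries, so that 20 libraries were used. Per the labels, libraries were made from poly(A) RNA with an unstranded TruSeq kit, but the same passage speaks of DC samples, 3 for each group, which are neither the cells nor the numbers of this series. The labels give no batch, date or litter, so that such a difference between groups cannot be told apart from the groups themselves. The markers used for the sort are not given in the sources used here.

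The deposited values are raw counts per gene symbol, whole numbers at or above 0, in 2 tables of 49568 genes each with 1 column per library. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.0p3 with featureCounts, DESeq2 1.12.4 and the genome build GRCm38.p5. The order, the annotation and the settings of these steps are not given in the sources used here. Both tables list the same symbols in the same order and were joined. Of the symbols, 26 had been turned into dates, and these held at most 0.156% of a library's counts. They were kept under those names. Coordinates, gene types, GC content and transcript length came from GENCODE M21 (GRCm38), in which 47114 of the symbols were found once.

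Library totals ranged from 13712668 to 21622653 counts, and values in counts scaled per library (CPM) below 1 rest on few reads and are imprecise. The spread between replicates, not depth, sets the precision of most values. The common biological coefficient of variation was 32.5% in the LT-HSC fit, 29.2% in the MPP fit and 33.8% in the fit of all libraries. The counts carry no molecular identifiers, so that counting error understates the error of a value.

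Comparisons used edgeR 4.0.16 in R 4.3.3 with the filter filterByExpr, TMM normalization, robust dispersions and the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Ahr-KO was compared with WT within each population, on its 10 libraries. MPP was compared with LT-HSC within each genotype, and the Ahr-KO effect was compared between the populations, in 1 fit of all 20 libraries with 4 groups. Standard errors of log2 fold changes are the fold change divided by the square root of F. Values per library are CPM on TMM-scaled totals, given as mean and SD.

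Before the data were examined, the comparisons, the alternatives, 30 gene lists and the rule for named genes were fixed. The lists cover AHR signalling, the cell cycle, markers of stem cells, progenitors and mature cells, stress, metabolism, ribosomes, histones and regulators. A list needed at least 5 tested members, which 29 lists had in each comparison. The remaining list checked the sex of the animals. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. The calls were repeated with the correlation estimated for each list, and with fry. Calls of single members are given over all genes tested and adjusted over the list alone.

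Genes were named by the following rule. In each Ahr-KO comparison Ahr, Aurka, Ccnb1, Cdk1 and Plk1 are named whatever their result. In every comparison the called genes with a mean of at least 5 CPM are ranked by fold change, predicted genes and pseudogenes left out, and the 8 highest and 8 lowest are eligible. Of each list, up to 3 called members with the smallest p are eligible, or the single member with the smallest p where none was called. Up to 5 genes with the smallest p are eligible in the comparison of effects, and up to 8 of those called in both populations. The same rule was applied to the LT-HSC comparison without the library WT LT-HSC 1. Genes named outside the rule are marked as chosen after their values were seen.

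Alternatives replaced 1 choice at a time, though those that replaced the test brought further changes with them, DESeq2 its own size factors and voom its weights for libraries: DESeq2 size factors in edgeR, no filter, a filter of at least 5 CPM in at least 5 libraries, DESeq2 1.42.0 with its Wald test on the genes kept by filterByExpr, limma voom with sample quality weights, all libraries in 1 fit, each replicate left out in turn, a fold change of at least 1.5, and 1 surrogate variable from sva 3.50.0. A further alternative took the replicate number as a block and, where the groups do not share all numbers, also left out the libraries whose number only 1 group has. Some alternatives were chosen after seeing the data: leaving out Ahr-KO LT-HSC 2 and 3, leaving out these and WT LT-HSC 1, DESeq2 without the prior filter, and robust moderation after voom. Counts were also simulated from the mean and dispersion of each gene and the library sizes, without correlation between genes or a library that stands apart. In these simulated data the Aurora A and G2/M list was lowered 1.25-fold, and 50 genes each were changed 1.5-fold, 2-fold, 3-fold and 4-fold. The LT-HSC fit recovered 14%, 36%, 64% and 88% of these, and called 2 genes that were not changed. The MPP fit recovered 20%, 46%, 70% and 80%, and called 6 genes that were not changed. So many changed genes ease the adjustment, so that these shares need not hold for the real data. Results were also recomputed over 100 splits of the libraries into groups of the same sizes, drawn with a fixed seed and including the real one. No column of the tables was left out.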

Results

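The series profiled LT-HSC, the rare bone marrow cells that renew themselves and all blood lineages, and MPP, their progeny that keep all lineages open but renew little. Both were taken from WT mice and from mice labelled as knockouts of Ahr, which encodes a ligand-activated transcription factor. Its stated interest is the set of genes through which AHR acts on stem cell function and proliferation, with the kinase Aurora A and the passage of cells from G2 into mitosis in its title. Each of the 4 groups has 5 libraries. Total counts per library ranged from 18105914 to 21622653 in WT LT-HSC, from 16133048 to 21484304 in Ahr-KO LT-HSC, from 15496924 to 20375242 in WT MPP, and from 13712668 to 20738468 in Ahr-KO MPP.

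Transcripts of the targeted gene were present in every library. Ahr, on chromosome 12 from 35497974 to 35535038, had 20.8 to 36.6 CPM in the WT LT-HSC libraries (mean 26.5 ± 6.35, SD, n = 5) and 18.5 to 29.7 CPM in those labelled Ahr-KO (23.6 ± 4.14, SD, n = 5). In MPP it had 5.80 to 14.2 CPM in WT (9.81 ± 3.66, SD, n = 5) and 9.80 to 19.2 CPM in Ahr-KO (15.9 ± 3.91, SD, n = 5). Neither difference passed the test, with a log2 fold change of -0.15 ± 0.18 (SE, adjusted p = 0.861) in LT-HSC and 0.69 ± 0.27 (adjusted p = 0.663) in MPP. The labels do not give the allele, and deletion of part of a gene can leave its transcript in place, so a count per gene need not check the label. The directions below are therefore those between libraries as labelled.

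**Figure D1:**
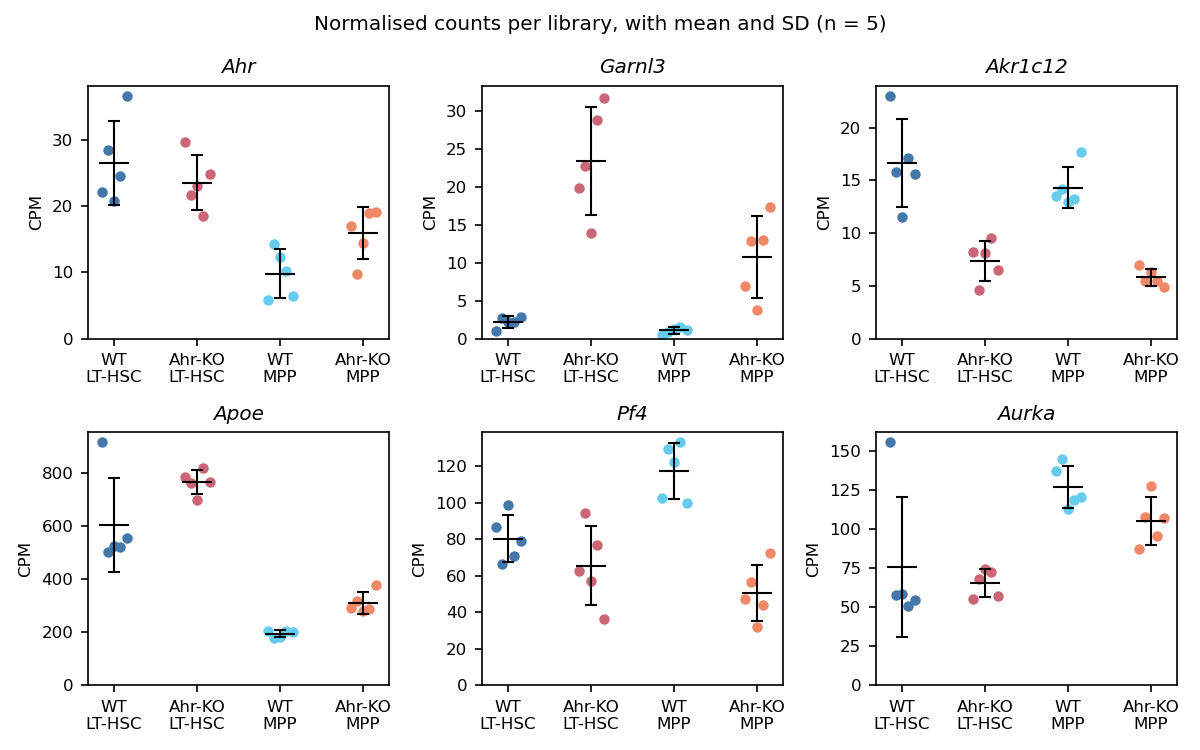
Normalised counts (CPM, vertical axes starting at 0) of 6 genes in each library of the 4 groups, with the mean and SD of 5 libraries as bars. Ahr is present in all libraries, Garnl3 is higher in the Ahr-KO libraries of both populations, and WT LT-HSC 1 has 155.5 CPM of Aurka.

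The first comparison asked which genes differ between Ahr-KO and WT LT-HSC. Garnl3, which encodes a protein with a GTPase-activating domain of the Rap type, was 10.8-fold higher in the Ahr-KO libraries, at 23.4 ± 7.10 CPM against 2.18 ± 0.749 (SD, n = 5), and all 5 Ahr-KO libraries lay above all 5 WT libraries. It lies on chromosome 2 from 32986224 to 33131654, and its log2 fold change of 3.43 ± 0.32 (SE, adjusted p = 0.00687) passed the test. No other gene did. The genes of the Aurora A and G2/M programme named in advance did not pass: Aurka, the Aurora A kinase itself, had a log2 fold change of -0.19 ± 0.30 (adjusted p = 0.907), Ccnb1, the mitotic cyclin B1, had -0.23 ± 0.32 (adjusted p = 0.890), and Cdk1 and Plk1 had -0.05 and -0.07 (adjusted p = 0.961 and 0.973). Csf3r, the receptor for the granulocyte colony-stimulating factor, did not pass either, at 125 ± 11.9 CPM in Ahr-KO against 66.02 ± 11.3 in WT, with a log2 fold change of 0.94 ± 0.13 and an adjusted p of 0.0950. Jun, an AP-1 transcription factor, stood at 65.3 ± 8.33 CPM against 143 ± 49.5 (log2 fold change -1.11 ± 0.22, adjusted p = 0.250).

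Leaving out WT LT-HSC 1 changed this comparison more than leaving out any other library. In WT LT-HSC 1 Aurka had 155.5 CPM against 50.5 to 58.3 in the other WT LT-HSC libraries, and Ccnb1 had 337 CPM against 103 to 123. That library correlated with the other WT LT-HSC libraries at r = 0.909 to 0.918, while no other pair within a group fell below 0.940, and mitochondrial transcripts made up 0.386% of its counts against 1.07% or more in the others. edgeR tested 16065 genes in LT-HSC and called 1, with 1422 genes at an unadjusted p under 0.05 where 803 are expected by chance. DESeq2 called 149 and limma voom with sample quality weights called 264. Without WT LT-HSC 1 edgeR called 203 genes, of which 70 were higher and 133 lower, without WT LT-HSC 5 or 6 it called 0, and without Ahr-KO LT-HSC 7 it called 2. With Ahr-KO LT-HSC 2 and 3 left out beside WT LT-HSC 1, and so with fewer libraries, it called 32, of which 11 were higher and 21 lower.

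Aurka, Ccnb1, Cdk1 and Plk1 turned to positive values without WT LT-HSC 1, and did not pass the test, with log2 fold changes of 0.25 ± 0.10, 0.26 ± 0.12, 0.11 ± 0.09 and 0.37 ± 0.15 and adjusted p of 0.208, 0.257, 0.530 and 0.205. In this smaller comparison Garnl3 rose again (3.24 ± 0.24, adjusted p = 2.6e-04), and Csf3r rose by 0.84 ± 0.08 (adjusted p = 6.95e-04). Gpr160 (1.25 ± 0.24), the endothelial transcription factor gene Sox18 (1.17 ± 0.21), Tnfsf13os, Rnf208, the carboxylesterase gene Ces2g (0.89 ± 0.17), Them6 and the MHC class II gene H2-Ab1 (0.86 ± 0.15) were the other largest rises. The largest falls were those of Ankrd16 (-1.57 ± 0.21), Firre (-1.46 ± 0.27), Jun (-1.27 ± 0.14, adjusted p = 0.00406), the nuclear RNA Neat1 (-1.27 ± 0.26), Fam184a, the small GTPase gene Gem (-1.10 ± 0.15), Adamts10 and the splicing kinase gene Clk1 (-1.04 ± 0.18). Among list members, the erythroid and megakaryocytic factor gene Gata1 rose by 0.72 ± 0.14 (adjusted p = 0.0394). The immunoproteasome gene Psmb8 (0.36), the glutathione genes Gclm (0.39) and Gstp1 (0.26), and the ribosomal protein genes Rps26 (0.35), Rps13 (0.28) and Rpl26 (0.23) also rose. Hoxa9, a self-renewal factor gene (-0.46 ± 0.09, adjusted p = 0.0392), the LT-HSC marker Ctnnal1 (-0.40) and Pdk1 (-0.41), which restrains pyruvate oxidation, fell. Apoe, the apolipoprotein E gene, and Akr1c12, an aldo-keto reductase gene, were among the other calls (0.56 ± 0.05 and -1.01 ± 0.20, adjusted p = 6.95e-04 and 0.0392), and were chosen after their values were seen.

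As groups, genes of cytosolic ribosomal proteins were higher in Ahr-KO LT-HSC. All 79 tested members had positive values, with a median log2 fold change of 0.22. Camera gave an adjusted p of 1.0e-31, 0 members were called over all genes by edgeR, 31 were called when adjusted over the list alone, and the list had an adjusted p = 0.475 with an estimated correlation. fry, which asks only whether the members move one way, gave an adjusted p of 0.0345 for this list and for no other in this comparison. With WT LT-HSC 1 left out the median was 0.19 and 62 members were called adjusted over the list alone, and fry gave an adjusted p of 0.0182. Mitochondrially encoded genes had a median of 0.52 (camera adjusted p = 2.2e-06, adjusted p = 0.732 with an estimated correlation), and all 13 were positive. WT LT-HSC 1 held 3644 CPM of them, against 9470 to 11400 in the other WT and 11160 to 15000 in the Ahr-KO libraries, and with it left out the median was 0.29 (adjusted p = 2.2e-07). The interferon response list had a median of 0.14 (adjusted p = 0.0232, and adjusted p = 0.732 with an estimated correlation), with Oas3 at 0.60 ± 0.20 as its member with the smallest p. Immediate early genes, which respond within minutes to stress or cell isolation, had a median of -0.23 (adjusted p = 0.00701, and adjusted p = 0.732 with an estimated correlation). The T and NK cell list had a median of -0.12 and the oxidative phosphorylation list one of -0.01, although camera placed both higher, and neither passed. With that library left out camera called 10 lists where it had called 6, the oxidative phosphorylation list among them (adjusted p = 1.3e-16, 29 of 97 members called adjusted over the list alone), and none with the correlation estimated. Over 15 alternatives the ribosomal list was called in 14, the mitochondrially encoded genes in 13, the immediate early genes in 11 and the interferon list in 9.

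Genes of mature myeloid cells were high in 2 of the Ahr-KO LT-HSC libraries. The granulocyte-monocyte progenitor list (median 1.07, camera adjusted p = 5.8e-04) and the monocyte and macrophage list (median 1.25, adjusted p = 0.00184) were called higher, and both had an adjusted p = 0.732 with an estimated correlation. The summed neutrophil list stood at 1184 and 1639 CPM in Ahr-KO LT-HSC 2 and 3 and at 7.37 to 142 CPM in the 8 other LT-HSC libraries. Without those 2 libraries the progenitor list was not called (adjusted p = 0.690), and the monocyte list turned to the other direction (adjusted p = 0.756). Both were called in 11 of 15 alternatives, over which their adjusted p ranged from 6.8e-07 to 0.912 and from 8.3e-07 to 0.756. Ltf, a neutrophil granule gene, was at 78.0 ± 117 CPM against 0.549 ± 0.358, and Col1a1, a collagen of connective tissue, was at 2024 CPM in Ahr-KO LT-HSC 3 and at most 3.02 in the other 9 libraries. Neither Ltf (adjusted p = 0.451) nor Col1a1 (adjusted p = 0.474) passed.

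**Figure D2:**
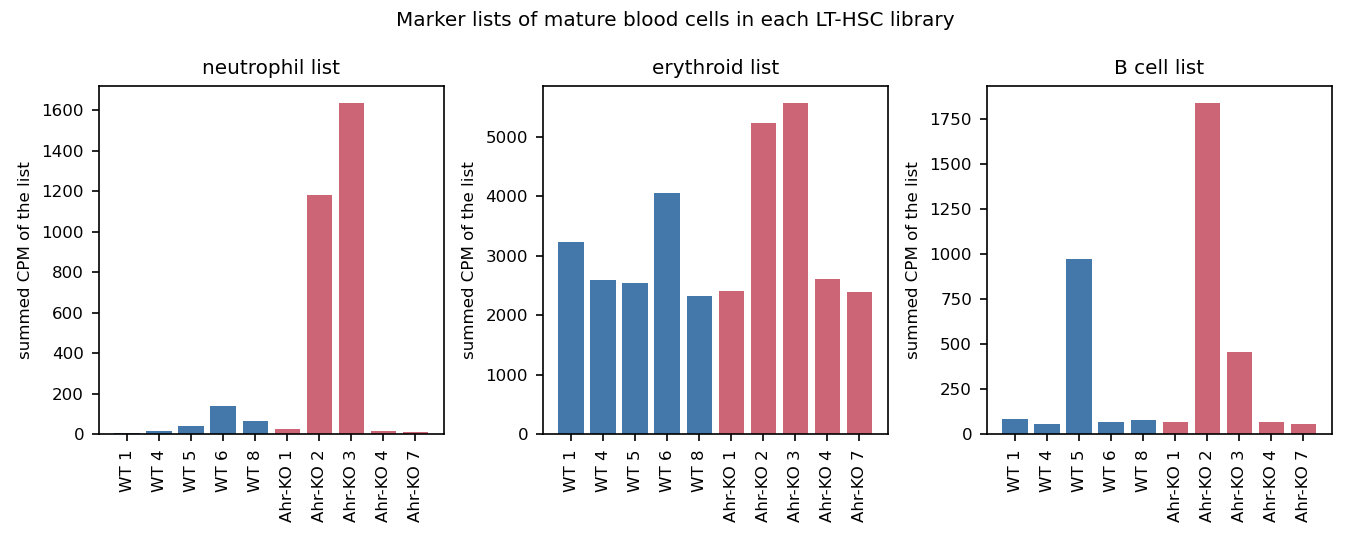
Summed normalised counts (CPM, axes starting at 0) of the neutrophil, erythroid and B cell marker lists in each of the 10 LT-HSC libraries. Ahr-KO LT-HSC 2 and 3 stand highest for the neutrophil list, at 1184 and 1639 CPM, and the B cell list is also high in WT LT-HSC 5, at 972 CPM.

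The Aurora A and G2/M phase list did not pass in LT-HSC. Its median was -0.10, 15 of its 58 members were positive, and 0 were called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.0516, and adjusted p = 0.890 with an estimated correlation). Without WT LT-HSC 1 the median was 0.05 and the adjusted p 0.426, in the other direction. The list was called lower without WT LT-HSC 6 or 8, or without Ahr-KO LT-HSC 2, 3 or 4, with adjusted p from 5.2e-04 to 0.0120, and over 15 alternatives the adjusted p ranged from 1.8e-04 to 0.890. S phase genes (median -0.04, adjusted p = 0.201), with the kinase gene Cdc7 at -0.50 ± 0.12, and quiescence genes (median -0.12, adjusted p = 0.201), with Ndn at 0.37 ± 0.11, did not pass either. LT-HSC markers (median -0.07, adjusted p = 0.400) and MPP markers (median 0.13, adjusted p = 0.201) did not pass. Ly6a, which encodes Sca-1, was at 0.60 ± 0.15 and Plac8 at 1.14 ± 0.42. AHR target genes had a median of -0.07 over 10 tested members (adjusted p = 0.866), and the classic targets Cyp1a1 and Cyp1b1 were too low to be tested. Xdh, the AHR target with the smallest p, was at 1.38 ± 0.62 with all libraries and at -0.26 without Ahr-KO LT-HSC 2 and 3.

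**Figure D3:**
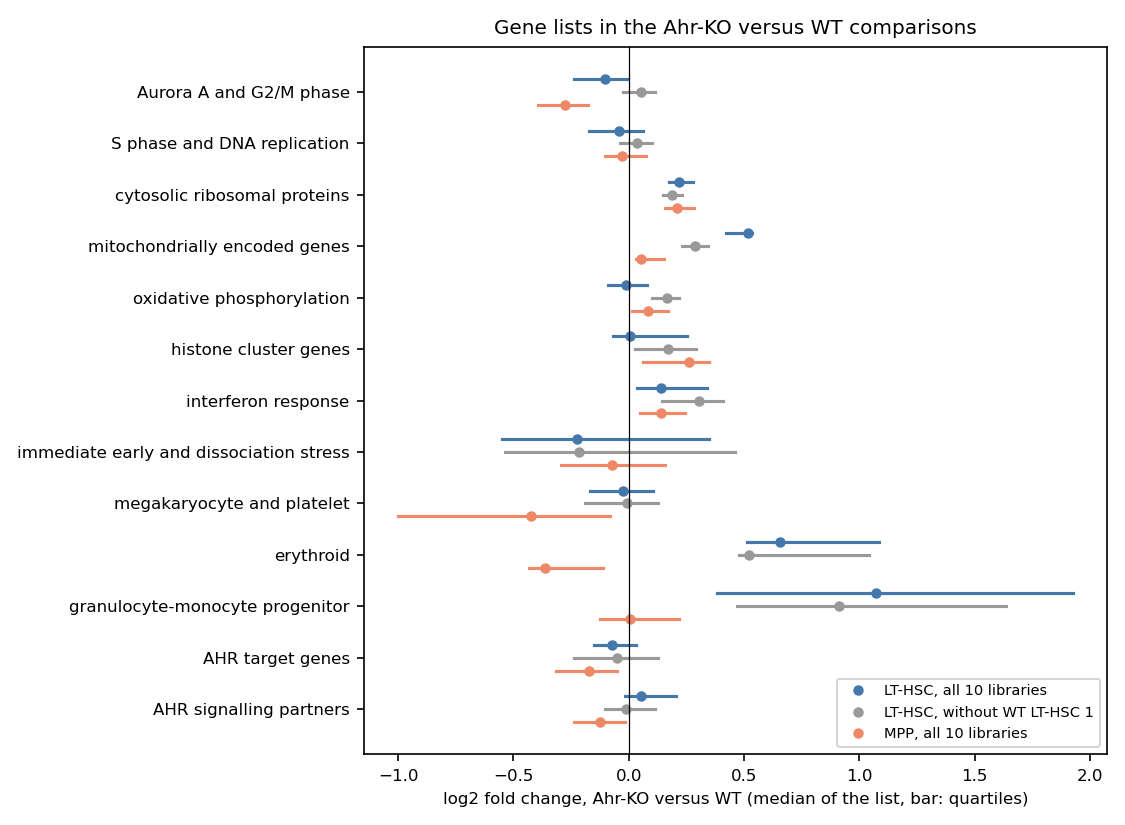
Median log2 fold change (Ahr-KO versus WT) of 13 gene lists, with bars from the lower to the upper quartile of the members, in LT-HSC, in LT-HSC without WT LT-HSC 1, and in MPP. The Aurora A and G2/M phase list lies at -0.28 in MPP, and at -0.10 and 0.05 in LT-HSC with and without WT LT-HSC 1.

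The second comparison asked the same of MPP. Garnl3 was again higher in Ahr-KO, 9.90-fold, at 10.8 ± 5.41 CPM against 1.07 ± 0.420 (SD, n = 5; log2 fold change 3.31 ± 0.43, SE, adjusted p = 0.0373). Arhgef25, a guanine nucleotide exchange factor gene on chromosome 10 from 127182525 to 127190083, rose from 3.98 ± 1.33 to 12.7 ± 2.08 CPM (1.66 ± 0.25, adjusted p = 0.0491). Apoe, the lipid carrier apolipoprotein E, on chromosome 7 from 19696109 to 19699188, rose from 193 ± 13.1 to 310 ± 40.5 CPM (0.68 ± 0.09, adjusted p = 0.0374). Akr1c12, an aldo-keto reductase gene on chromosome 13 from 4268176 to 4279433, fell from 14.3 ± 1.96 to 5.80 ± 0.807 CPM (-1.30 ± 0.17, adjusted p = 0.0373). Pf4, the platelet factor 4 gene on chromosome 5 from 90772435 to 90773383, fell from 118 ± 15.35 to 50.4 ± 15.2 CPM (-1.22 ± 0.18, adjusted p = 0.0491). For each of these 5 genes the 5 Ahr-KO libraries lay entirely on 1 side of the 5 WT libraries.

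Aurora A and G2/M genes were lower as a group in Ahr-KO MPP, though the libraries overlapped. The list summed to 7166 to 10540 CPM in WT MPP, highest in WT MPP 1, and to 6492 to 7528 CPM in Ahr-KO MPP. Of the 58 members 54 had negative values, with a median log2 fold change of -0.28 (camera adjusted p = 9.8e-20), and the list had an adjusted p = 0.728 with an estimated correlation. edgeR called 0 members over all genes, and 8 were lower when adjusted over the list alone. Over 14 alternatives the adjusted p of the list ranged from 2.0e-23 to 0.728, and it passed in 12, all but those with the correlation estimated and with fry. No single member therefore fell by the test over all genes: Cenpf, a kinetochore protein gene, was at 80.4 ± 13.5 CPM against 127 ± 19.99 (-0.66 ± 0.14, adjusted p = 0.342), Ccnb1 at 210 ± 28.6 against 303 ± 80.6 (-0.53 ± 0.15, adjusted p = 0.560), Plk1 at 92.3 ± 12.2 against 131 ± 32.4 (-0.50 ± 0.15, adjusted p = 0.568), Aurka at 105 ± 15.3 against 127 ± 13.4 (-0.27 ± 0.11, adjusted p = 0.675), and Cdk1 at 164 ± 9.64 against 182 ± 11.6 (-0.15 ± 0.08, adjusted p = 0.770). S phase and DNA replication genes did not move with them (median -0.03, adjusted p = 0.719), and Ung, the uracil glycosylase gene, was at 0.52 ± 0.17. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 20.5 ± 3.55 CPM against 10.7 ± 2.83 (0.94 ± 0.20, adjusted p = 0.342), and was called when adjusted over the quiescence list alone, whose own test did not pass (median -0.08, mean 0.02, adjusted p = 0.719). Histone cluster genes had a median of 0.26 with 57 of 61 positive (adjusted p = 2.7e-07, and adjusted p = 0.728 with an estimated correlation), with Hist1h1e at 0.70 ± 0.18.

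Megakaryocyte and platelet genes were also lower in Ahr-KO MPP, with a median of -0.42 (camera adjusted p = 1.3e-07, and adjusted p = 0.728 with an estimated correlation). Not every library went this way. The list summed to 1308 to 1698 CPM in WT MPP and 1153 to 1313 in Ahr-KO MPP 1 to 4, but to 1727 in Ahr-KO MPP 5. That library also had the most LT-HSC marker counts of the MPP libraries (2591 CPM against 1558 to 2121). Pf4 was the called member over all genes, and 7 of 20 were lower adjusted over the list alone. Vwf, the von Willebrand factor gene, was at 18.2 ± 8.58 CPM against 40.0 ± 14.9 (-1.14 ± 0.35, adjusted p = 0.591), and Gfi1b, a repressor needed for red cells and platelets, at -0.51 ± 0.12. The erythroid list had a median of -0.36 (adjusted p = 0.00167, and adjusted p = 0.728 with an estimated correlation), with the blood group gene Rhd at -1.02 ± 0.38. Ribosomal protein genes had a median of 0.21 with 78 of 79 positive (adjusted p = 1.2e-11, and adjusted p = 0.728 with an estimated correlation). In the MPP libraries with the strongest length bias their sum went with it. It was 19540 CPM in WT MPP 1 and 23770 in Ahr-KO MPP 5, where long transcripts were high for the group (Spearman correlation of 0.262 and 0.320 across genes). It was 32730 in WT MPP 5 and 33090 in Ahr-KO MPP 2, where they were low (-0.346 and -0.231). The highest sum, 33800 CPM, was that of Ahr-KO MPP 1 (-0.115). WT LT-HSC 1 went the other way, with the lowest sum in LT-HSC (22800 CPM) at -0.369. The relation was not tested. AHR signalling partners had a median of -0.13 (adjusted p = 0.0287, and adjusted p = 0.728 with an estimated correlation), with the coactivator gene Ncoa2 at -0.49 ± 0.15, while AHR target genes did not pass (median -0.17, adjusted p = 0.140), with Nqo1 at -0.35 ± 0.18. The monocyte and macrophage list (median 0.25, adjusted p = 0.0404, and adjusted p = 0.728 with an estimated correlation) and the interferon response list (median 0.14, adjusted p = 0.0436, and adjusted p = 0.759 with an estimated correlation) were higher. Over 14 alternatives each, the interferon list was called in 4, the monocyte and AHR partner lists in 7, the erythroid list in 10, and the megakaryocyte, ribosomal and histone lists in 12.

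The B cell list did not pass in MPP. It had a median of 0.27 and an adjusted p of 0.0515, with 10 of 15 members positive and 5 negative, 0 called by edgeR over all genes and 5 higher adjusted over the list alone. Immunoglobulin transcripts, which make up 1.27% to 6.13% of the counts in WT MPP, made up 0.350% to 1.499% in Ahr-KO MPP. The lymphoid priming list did not pass (median 0.00, adjusted p = 0.175), with Ccr9 at -1.98 ± 0.50. Per2, a clock gene, was at 0.49 ± 0.11 and was called when adjusted over the circadian list alone.

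edgeR tested 16077 genes in MPP, and 1065 had an unadjusted p under 0.05 where 804 are expected by chance. DESeq2 called 50 genes and voom with quality weights called 8. The 5 calls rest on the full set of libraries. Without WT MPP 1 edgeR called 1 gene, which was none of the 5, and without Ahr-KO MPP 3 it called 1 of the 5. Without Ahr-KO MPP 5 it called 4, of which 3 were among the 5, and without any other single library it called 0. Garnl3 had a log2 fold change of 3.08 to 3.53 over 17 alternatives and was called in 6 of them. Camera called 8 lists in MPP, and 5 without WT MPP 2, Ahr-KO MPP 1 or Ahr-KO MPP 2.

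The third comparison asked whether the Ahr-KO difference itself differs between MPP and LT-HSC. edgeR called 0 of 17416 genes, with 1125 at an unadjusted p under 0.05 where 871 are expected by chance, and DESeq2 called 51. The genes with the smallest p, each at an adjusted p of 0.296, were Reep2 (-1.249 ± 0.24), Acap1 (0.68 ± 0.13), Sfxn4 (1.21 ± 0.24), Tbce (0.91 ± 0.18) and Faxc, which had 0 counts in all Ahr-KO MPP libraries and 0.147 ± 0.0846 CPM in WT MPP. Camera called 11 lists, 10 of them lower in the MPP effect and 1 higher, and none was called with an estimated correlation (lowest adjusted p = 0.747 with an estimated correlation) or by fry. The Aurora A and G2/M list was among them (median -0.11, adjusted p = 0.00187). The difference between MPP and LT-HSC for that list thus passed camera alone. Without WT LT-HSC 1 camera called 4 lists, without Ahr-KO LT-HSC 2 or 3 it called 7, and without Ahr-KO MPP 4 it called 6.

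Garnl3 was the single gene called in both populations, and without WT LT-HSC 1 there were 3. Fisher's exact test, two-sided, gave p = 2.0e-04 for its being shared among 15289 genes tested in both. At an unadjusted p under 0.01 in both populations there were 20 genes where 4.59 are expected (Fisher's exact p = 3.8e-08), and 19 of them had the same direction (exact binomial p = 4.0e-05, two-sided), although genes are not independent. These tests also take the 2 populations as independent. The labels do not say whether LT-HSC and MPP libraries of the same genotype and number come from the same mouse. The LT-HSC and MPP libraries of the same number were the closest of their pairings in 5 of 8 cases in Ahr-KO and 0 of 6 in WT. Shared mice could raise such an overlap. Across all genes the fold changes of the populations hardly correlated (r = 0.05, across genes, which are not independent replicates). The following were named after their values were seen: Akr1c12 (-1.15 ± 0.23 in LT-HSC) and its neighbour Akr1c13 (-1.98 ± 0.39 and -1.81 ± 0.32), the insulin-degrading enzyme gene Ide (-0.80 ± 0.10 and -0.81 ± 0.18), Gem (-1.01 ± 0.18 and -0.89 ± 0.22), the surrogate light chain gene Vpreb3 (3.55 ± 0.95 and 1.84 ± 0.52), and Ifitm1 (0.32 ± 0.09 and 0.52 ± 0.08). Csf3r was at 0.94 ± 0.13 and 0.34 ± 0.10. Also named after their values were seen, 6 of the 19 genes, Hdac9, G2e3, Dtd2, Srp54a, Srp54b and 1700047I17Rik2, lie on chromosome 12 between 34.0 and 55.2 Mb, the chromosome arm that holds Ahr at 35.5 Mb.

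**Figure D4:**
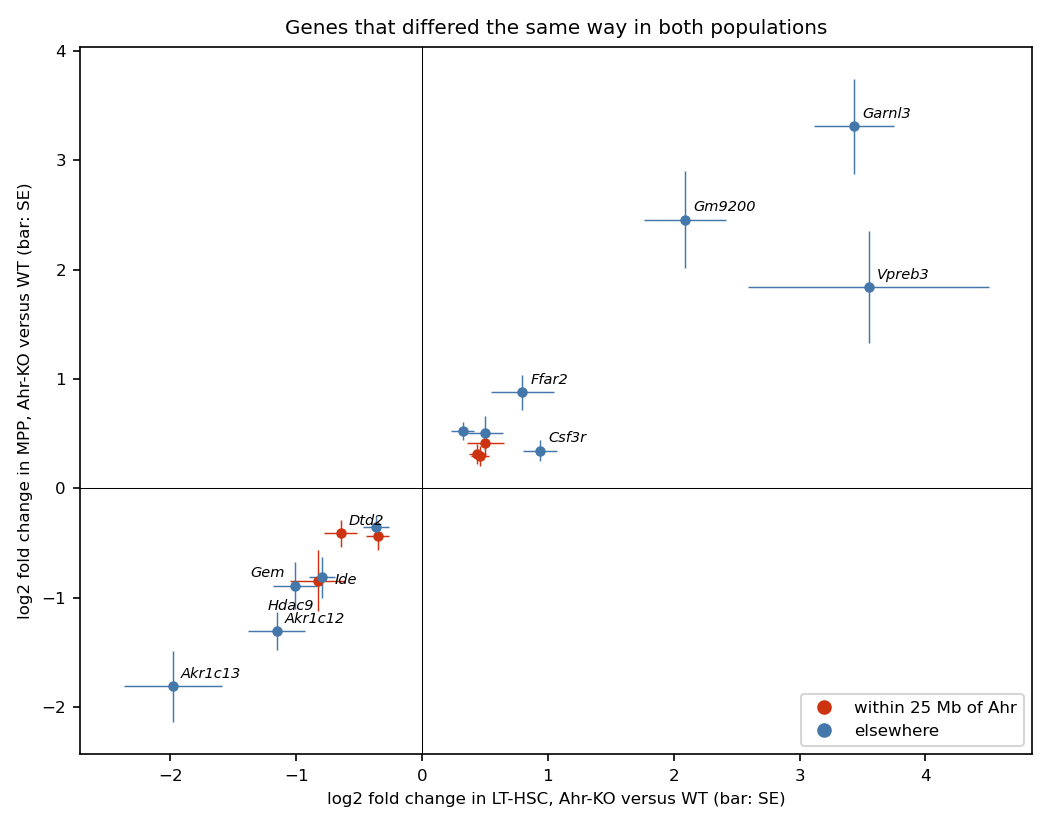
Log2 fold change (Ahr-KO versus WT) in LT-HSC against that in MPP, with SE bars, for the genes with an unadjusted p under 0.01 and the same direction in both. Genes within 25 Mb of Ahr are in red, and Col1a1, at 8.84 in LT-HSC, lies outside the range drawn.

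The fourth comparison described how MPP differ from LT-HSC within each genotype. In WT, markers of LT-HSC were lower in MPP for 31 of 33 members of the list (median -1.98). Pdzk1ip1 fell from 176 ± 18.1 to 32.4 ± 2.89 CPM (-2.44 ± 0.12, SE, adjusted p = 1.1e-10), and Mllt3, which maintains stem cells in culture, fell by 2.55 ± 0.16 and the endothelial-type adhesion gene Esam by 2.04 ± 0.16. MPP markers rose, with 11 of 15 called higher (median 1.498): Flt3, the cytokine receptor that marks lymphoid-competent progenitors, went from 57.1 ± 9.13 to 480 ± 70.6 CPM (3.07 ± 0.17, adjusted p = 3.6e-10) and Cd34 rose by 1.498 ± 0.12. Both lists were also called with the correlation estimated (adjusted p = 0.0190 with an estimated correlation). edgeR called 3876 of 17416 genes, 1916 higher and 1960 lower in MPP.

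**Figure D5:**
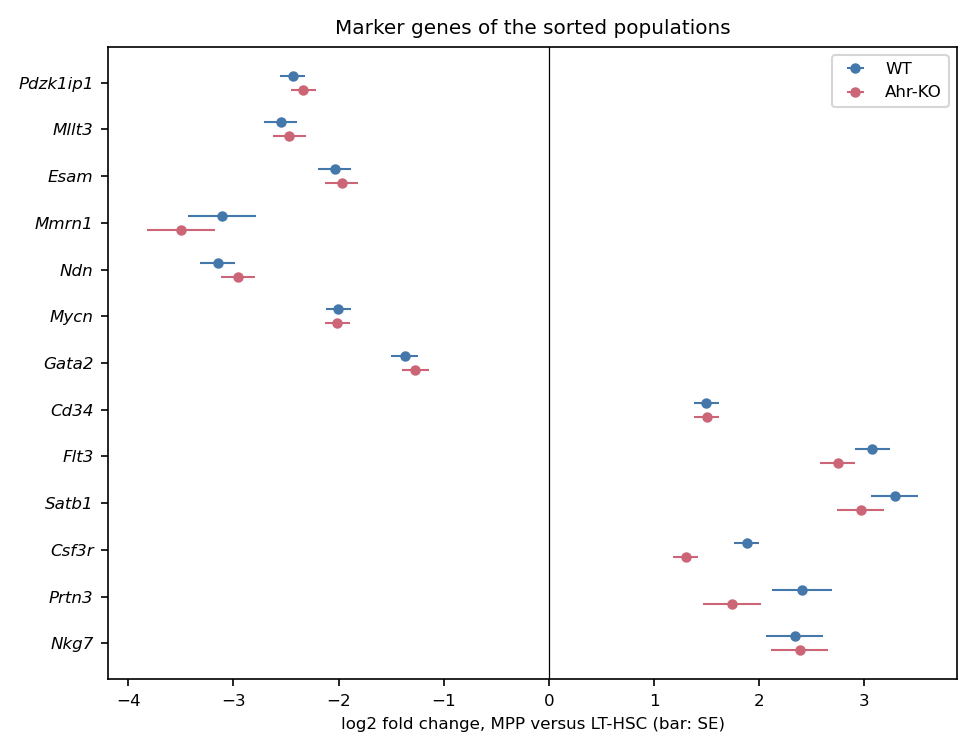
Log2 fold change (MPP versus LT-HSC) with SE bars for 13 marker genes in WT and in Ahr-KO. Stem cell and megakaryocyte genes such as Pdzk1ip1, Mllt3 and Mmrn1 lie below 0 and Flt3, Satb1 and Csf3r above 0 in both genotypes.

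Lymphoid and granulocyte-monocyte genes were higher and megakaryocyte genes lower in WT MPP at the preset correlation, and none of these 3 lists was called with the correlation estimated. The lymphoid priming list was higher (14 of 20 called, median 3.14), with the chromatin organiser Satb1 at 3.29 ± 0.23. It holds the immunoglobulin gene Ighm, which is also on the B cell list (chosen after its values were seen). Ighm made up 8898 of the 12320 CPM of the list in WT MPP 1 and 29710 of 36070 in WT MPP 3. How far B cell transcripts account for the rise of the list was not tested. The granulocyte-monocyte progenitor list was higher (16 of 18 called, median 2.97), with Csf3r at 1.88 ± 0.12, Cebpa at 3.62 ± 0.38 and the granule protease gene Prtn3 at 2.41 ± 0.28. Megakaryocyte and platelet genes were lower (12 of 20 called, median -0.87): Mmrn1 fell by 3.11 ± 0.32 and Gp5 by 1.56 ± 0.19. These 3 lists had camera adjusted p of 2.4e-10, 4.3e-12 and 1.9e-08, and adjusted p = 0.0540, adjusted p = 0.128 and adjusted p = 0.0754 with an estimated correlation. Erythroid genes as a list did not pass (median -0.25, mean 0.01, adjusted p = 0.753), though Car2 (-0.99) and Epor (-0.83) fell. Of the regulators, Mycn (-2.01 ± 0.12) and Gata2 (-1.37 ± 0.13) fell.

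Cell cycle genes were higher in WT MPP than in WT LT-HSC. Of the Aurora A and G2/M list 45 of 58 members rose (median 0.88, adjusted p = 4.8e-25, and adjusted p = 0.0754 with an estimated correlation), with Pkmyt1, a kinase that holds Cdk1 inactive, at 1.21 ± 0.13, the cohesin protector gene Sgol1 at 1.07 ± 0.11 and Incenp, of the chromosomal passenger complex, at 0.89 ± 0.10. Of the S phase list 20 of 45 rose (median 0.35, adjusted p = 1.8e-08, and adjusted p = 0.233 with an estimated correlation), with Cdc7 at 1.02 ± 0.15 and Cdc45 at 0.89 ± 0.15. The cell cycle inhibitor gene Cdkn1c fell by 3.35 ± 0.34 and the growth suppressor gene Ndn by 3.15 ± 0.16, while Ccnd2, a G1 cyclin, fell by 0.96 ± 0.09 and Cdkn1a rose by 1.90 ± 0.21. Histone cluster genes rose (18 of 62 called higher, median 0.48, adjusted p = 6.1e-06, and adjusted p = 0.434 with an estimated correlation). Immediate early genes were lower (9 of 25 called, adjusted p = 0.0139, and adjusted p = 0.401 with an estimated correlation), with Egr1 at -3.12 ± 0.42. Without WT LT-HSC 1, the LT-HSC library with the most Aurka, 5323 genes were called in this contrast. Oxidative phosphorylation genes (median 0.12, adjusted p = 0.0210) and mitochondrially encoded genes (median 0.40, adjusted p = 0.0169) were called higher, and had adjusted p = 0.751 and adjusted p = 0.578 with an estimated correlation. Over 13 alternatives they were called in 4 and 9.

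Mature cell genes accounted for the largest rises in WT. The 8 largest were all immunoglobulin variable genes, such as Igkv15-103, at 753 ± 621 CPM in MPP against 0.145 ± 0.121 (12.27 ± 0.89, adjusted p = 1.8e-08). For 4 others of the 8 all WT LT-HSC libraries held 0 counts, and no fold is given. Lists of B cells (median 3.71, adjusted p = 8.6e-06), neutrophils (3.35, adjusted p = 2.6e-04), monocytes and macrophages (1.81, adjusted p = 1.4e-04), mast cells and basophils (2.77, adjusted p = 0.00199) and T and NK cells (0.49, adjusted p = 0.0200) were called higher, and had an adjusted p from 0.233 to 0.459 with an estimated correlation. The mast cell protease gene Cpa3 rose by 2.95 ± 0.40 and the cytotoxic granule gene Nkg7 by 2.34 ± 0.27, whereas Klrb1c fell by 1.76 ± 0.38. The largest falls in WT were those of Efna1 (-7.04 ± 0.87), the Wnt inhibitor gene Sfrp1 (-5.87 ± 0.81), Ocln (-5.42 ± 0.80), Clip3, Sult1a1 (-4.65 ± 0.44), Evc2 and Sorbs2.

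In Ahr-KO the same contrast called 4041 genes, 2183 higher and 1858 lower in MPP. LT-HSC markers were lower in 32 of 33 members (median -1.97), with Pdzk1ip1 at -2.34 ± 0.12, Mllt3 at -2.47 ± 0.16 and Esam at -1.97 ± 0.16, and 11 of 15 MPP markers were higher (median 1.502), with Flt3 at 2.74 ± 0.16. Megakaryocyte and platelet genes were lower in 15 of 20 (median -1.46), with Mmrn1 at -3.50 ± 0.33 and Gp9 at -1.80 ± 0.19. These 3 lists were also called with the correlation estimated (adjusted p = 0.0160 with an estimated correlation). The Aurora A and G2/M list had 36 of 58 members higher (median 0.66, adjusted p = 2.7e-16, and adjusted p = 0.195 with an estimated correlation), with Kif20b at 1.40 ± 0.12 and Mad2l1 at 0.85 ± 0.10. The S phase list had 25 of 45 higher (median 0.40, adjusted p = 8.4e-10, and adjusted p = 0.195 with an estimated correlation). Histone cluster genes had 35 of 62 higher (median 0.64, adjusted p = 2.7e-10, and adjusted p = 0.325 with an estimated correlation).

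Lymphoid priming genes were higher in Ahr-KO MPP (11 of 20, median 2.23, adjusted p = 2.5e-09, and adjusted p = 0.0617 with an estimated correlation), with Satb1 at 2.96 ± 0.22. Here too the list holds Ighm, at 1505 to 6912 CPM in Ahr-KO MPP, and the part of B cell transcripts was not tested. Progenitor genes of granulocytes and monocytes were higher too (11 of 18, median 1.47, adjusted p = 4.9e-09, and adjusted p = 0.204 with an estimated correlation), with the repressor gene Gfi1 at 2.34 ± 0.28. Myeloid lists stood in a comparison where Ahr-KO LT-HSC 2 and 3 carry mature blood genes. The neutrophil list had a median of -0.25 and a mean of -0.01 while camera called it higher (adjusted p = 0.00381, and adjusted p = 0.509 with an estimated correlation), with 0 of 15 members called by edgeR. B cell genes were higher in 7 of 15 (median 2.505, adjusted p = 1.7e-06, and adjusted p = 0.195 with an estimated correlation), with Vpreb1 at 2.505 ± 0.46 and Igll1 at 3.87 ± 0.84. The monocyte and macrophage list (median 0.53, adjusted p = 0.00777), the T and NK cell list (0.86, adjusted p = 0.0242), the mast cell and basophil list (1.09, adjusted p = 0.00777) and the oxidative phosphorylation list (0.21, adjusted p = 0.00246) were also called higher. The interferon response list (-0.14, adjusted p = 0.0237) and the glycolysis list (-0.17, adjusted p = 0.0242) were called lower, and none of these 6 was called with an estimated correlation. The connective tissue genes Col1a1, Col1a2, Col11a1 and Sparc were among the largest falls and rest on Ahr-KO LT-HSC 3, which held 2024, 1680, 50.3 and 352 CPM of them against at most 3.02, 24.6, 1.94 and 14.004 in the other LT-HSC libraries. For Col1a1 the value of -7.92 ± 2.07 became 0.38 without that library, and over the alternatives Col1a2, Col11a1 and Sparc moved to as little as -1.93, -0.69 and -0.65. Evc2 (-8.79 ± 1.14), Efna1 (-4.82 ± 0.72), Scrn1 and Plcl1 (-4.28 ± 0.41) were the other largest falls.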

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

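The tests of lost transcripts and of an MPP share in WT LT-HSC 1, all 3 tests of the blood cell genes of Ahr-KO LT-HSC 2 and 3, and all 3 tests of the genes that differ in both populations were chosen only after the result was seen. A library is listed here when its gap to the nearest other library of its group was large against the range of the group, by Dixon's ratio. Of 148 groups of values tested 17 met this, where chance gives about 1 in 20, or 7. WT LT-HSC 1 accounts for 9 of the 17.

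In WT LT-HSC 1 the highest values of its group were those of Aurka (155.5 CPM, next 58.3), Ccnb1 (337.5, next 123), Cdk1 (137.7, next 91.35), Plk1 (146.5, next 57.7) and Hoxa9 (116.7, next 76.35). The lowest were those of Hsp90ab1 (1255 CPM, next 1330), Csf3r (46.42, next 68.5) and Rps26 (120.1, next 148.7), and the share of mitochondrial transcripts (0.3863%, next 1.07%). A share of MPP among the sorted cells as the main cause is argued against by the correlation across genes. The deviation of this library had a Spearman correlation of 0.1265 with the MPP minus LT-HSC difference, against -0.0314 to 0.0935 in the other 4. Markers, chosen after their values were seen, were mixed. Flt3, which is at 266 to 553 CPM in MPP, was at 43.28 CPM in it against 53.8 to 65.7 in the other 4. Cd34 was at 470 CPM against 302 to 394, and the MPP marker list summed to 2662 CPM against 2187 to 2467. The LT-HSC marker list summed to 5426 CPM against 5874 to 6216, so that a smaller share stays open. An uneven loss of transcripts is a candidate explanation, since 317 genes with at least 20 counts on average in the other 4 WT LT-HSC libraries had 0 counts in it, against 8 to 21 such genes in each of those 4. Bias by GC content or transcript length cannot be told apart, as these explained 17.24% of the variance of its deviation, a value between the limits set for and against, and 3.11% to 7.38% in the other 4. No biological explanation was tested, because the labels give this animal no difference from the others.

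In Ahr-KO LT-HSC 3 Col1a1 stood at 2024 CPM (next 3.02), and in Ahr-KO LT-HSC 2 immunoglobulin genes made up 0.368% of the counts (next 0.0949%). Both libraries also held high neutrophil genes, such as Ngp, chosen after its values were seen, at 247.9 and 406.4 CPM against at most 19.96 in the 8 other LT-HSC libraries. The Ahr-KO genotype as a cause acting in all Ahr-KO libraries is argued against, since the other 3 lay above all 5 WT libraries for 0 of 6 lists of mature blood cells. For neutrophil, erythroid, and monocyte and macrophage genes those 3 stood at 12.3 to 27.1, 2396 to 2606 and 473.5 to 585 CPM. The WT libraries stood at 7.37 to 142, 2322 to 4063 and 529.6 to 716 CPM. An effect in only some Ahr-KO animals cannot be told apart, since Ahr-KO LT-HSC 2 and 3 were picked for their high values. A share of MPP as the whole cause is argued against too, since all 3 lists that were higher in both libraries than in the 8 others (neutrophil at 1184 and 1639 CPM, erythroid at 5226 to 5574, monocyte and macrophage at 2288 to 2512) were also higher than in all 10 MPP libraries (at most 943.5, 2631 and 1111 CPM). Carry-over of mature blood cells or their RNA may explain the pattern, as it adds transcripts and takes none away: of the genes outside the 6 lists that lay at least 2-fold beyond all 8 others in both libraries 100% were higher (128 genes, and 0 lower), where none of the 44 other pairs of LT-HSC libraries had more than 6 higher. A share of myeloid progenitors beside it stays open, since the deviation of the 2 libraries had the highest Spearman correlations with the MPP minus LT-HSC difference (0.3252 and 0.2661), and the granulocyte-monocyte progenitor list summed to 4253 and 4019 CPM against at most 2456 in the 8 others and 5049 to 14360 in MPP.

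For single genes, mt-Nd2 stood at 172.5 CPM in Ahr-KO LT-HSC 7 (next 141.1), Akr1c12 at 17.71 CPM (next 14.2) and Ung at 12.3 CPM (next 9.46) in WT MPP 5, and Ccr9 at 8.528 CPM in WT MPP 1 (next 3.31). Immunoglobulin genes made up 0.1368% of the counts in WT LT-HSC 5 (next 0.00411%) and 6.134% in WT MPP 3 (next 1.95%).

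For gene lists, camera at the preset correlation found the Ahr-KO effect to differ between MPP and LT-HSC for 11 lists. It was lower in MPP for megakaryocyte and platelet genes (adjusted p = 5.983e-05), granulocyte-monocyte progenitor genes (2.833e-04), mitochondrially encoded genes (8.404e-04), the Aurora A and G2/M list (0.001872) and neutrophil genes (0.008582). It was also lower for AHR signalling partners, erythroid genes, monocyte and macrophage genes, and cytokine, niche and TGF-beta receptors (0.01183 each) and for lymphoid priming (0.04179), and was higher for histone cluster genes (0.0146). With an estimated correlation none of the 11 was called. Without WT LT-HSC 1, Ahr-KO LT-HSC 2 and 3 the erythroid and monocyte lists passed in the other direction (adjusted p = 0.0127 and 0.0486), and the receptor, progenitor, neutrophil and lymphoid lists also turned, without passing (0.921, 0.537, 0.0508 and 0.573).

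The third pattern is the set of 19 genes with an unadjusted p under 0.01 and the same direction in both populations. The blood cell genes of Ahr-KO LT-HSC 2 and 3 as its cause are argued against, since 17 of the 19 kept their direction and an unadjusted p under 0.05 in LT-HSC without those libraries, Vpreb3 and Col1a1 being the exceptions. For 6 of the genes, DNA carried along with the Ahr locus from another strain is a candidate explanation: 6 lay within 25 Mb of Ahr where 0.172 are expected, with an odds ratio of 52.71 (Fisher's exact p = 1.2e-08), and no window on another chromosome held more than 2. The test counts the 6 as independent, although Srp54a, Srp54b and 1700047I17Rik2 lie next to each other, so that this p is too small. Reads shared between neighbouring copies cannot be told apart from a change of each gene for 5 of the 19 (Akr1c12, Akr1c13, Srp54a, Srp54b and 1700047I17Rik2), which lie near another gene of the set. An effect of AHR itself stays open, as untested, for the 11 genes that lie elsewhere and kept their direction and p, Garnl3 among them. For these genes it cannot be told apart from any other difference between the WT and Ahr-KO mice, as the labels give no litter or allele.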

How the results depend on the processing

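The alternatives without Ahr-KO LT-HSC 2 and 3, without these and WT LT-HSC 1, DESeq2 without the prior filter, and voom with robust moderation were chosen only after the result was seen. The number of genes called between Ahr-KO and WT rests on the tool and on single libraries. With 5 libraries per group 36% of 2-fold changes were recovered in LT-HSC and 46% in MPP in simulated data. Those data held no library that stands apart and many changed genes, so that these shares need not hold for the real data. For changed results the cause was not tested.

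For Ahr-KO versus WT in LT-HSC edgeR called 1 gene. It was 3 with RLE size factors, 4 without a filter, 3 with the stricter filter, 149 with DESeq2, 121 with DESeq2 without the prior filter, 264 with voom and quality weights, 305 with robust moderation after voom, 14 in the fit of all libraries, 62 with 1 surrogate variable, 0 to 203 leaving out 1 library, and 32 without WT LT-HSC 1, Ahr-KO LT-HSC 2 and 3. For MPP it called 5, and 3 with RLE size factors, 50 with DESeq2, 86 with DESeq2 without the prior filter, 8 with voom and quality weights, 0 with 1 surrogate variable, and 0 to 4 leaving out 1 library. For the difference of the Ahr-KO effect DESeq2 called 51 genes where edgeR called 0. Genes called in both populations were 6 with DESeq2 and 3 without WT LT-HSC 1, where edgeR called 1.

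For lists, leaving out 1 library gave 5 to 10 calls in LT-HSC, 5 to 11 in MPP and 4 to 14 for the difference of effects. With an estimated correlation there were 0, 0 and 0, and 2 and 3 for MPP versus LT-HSC in WT and Ahr-KO, and fry called 1, 0 and 0, and 19 and 18 for these 2, where camera called 16 and 16.

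With the replicate number as a replicate block edgeR called 0 genes in MPP, on all 10 libraries. In LT-HSC it called 0 and for MPP versus LT-HSC in WT 113, but these used only the numbers that both groups share (1 and 4, and 1, 4 and 5), so that libraries were left out as well and the change is not put down to the replicate block. The libraries of the same number were the closest of their pairings in 0 of 4 cases for WT with Ahr-KO in LT-HSC and 0 of 10 in MPP. These pair different animals. For LT-HSC with MPP it was 0 of 6 in WT and 5 of 8 in Ahr-KO. The numbers thus need not pair libraries in WT, while shared mice stay open in Ahr-KO. On the 4 LT-HSC libraries numbered 1 and 4, WT LT-HSC 1 among them, with the replicate block, these values changed sign: Them6 -0.17, H2-Ab1 -0.23, Firre 0.23, Neat1 0.30, Fam184a 0.17, Adamts10 0.22, Psmb8 -0.14, Ltf -0.13 and Col1a1 -0.0284.

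In LT-HSC Aurka, Ccnb1, Cdk1 and Plk1 turned positive, at 0.23, 0.24, 0.10 and 0.35 with voom and quality weights, at 0.19, 0.19, 0.0732 and 0.30 with 1 surrogate variable, and at 0.15, 0.0903, 0.0325 and 0.19 without WT LT-HSC 1, Ahr-KO LT-HSC 2 and 3. Leaving out 1 library they ranged from -0.32 to 0.25, -0.36 to 0.26, -0.12 to 0.11 and -0.20 to 0.37, the highest being without WT LT-HSC 1, and Psmb8 from -0.0487 to 0.36. Without Ahr-KO LT-HSC 2 and 3 Xdh was at -0.26, Ltf at -0.0274 and Col1a1 at -0.45, and without WT LT-HSC 1 as well Xdh was at -0.39 and Ltf at -0.28. For MPP versus LT-HSC in Ahr-KO Col1a1 ranged from -8.68 to 0.38 leaving out 1 library, the highest being without Ahr-KO LT-HSC 3, and was at 1.32 without 2 and 3.

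Lists that changed direction in LT-HSC were the Aurora A and G2/M list without WT LT-HSC 1 (adjusted p = 0.426, where leaving out 1 library gave 5.2e-04 to 0.426), the monocyte list without Ahr-KO LT-HSC 2 and 3 (0.756), and the monocyte and granulocyte-monocyte progenitor lists without all 3 libraries (0.548 and 0.912). For the difference of effects without all 3 libraries they were lymphoid priming (0.573), granulocyte-monocyte progenitor (0.537), erythroid (0.0127), neutrophil (0.0508), monocyte (0.0486) and receptor genes (0.921). Over all alternatives of the Aurora A and G2/M list in LT-HSC the adjusted p ranged from 1.8e-04 to 0.890.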

Other observations

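The limits used in this part were set before the result was seen. The splits fixed before the data were examined were those of the 2 Ahr-KO comparisons, each on all its 10 libraries. The splits for MPP versus LT-HSC, for the difference of effects and for LT-HSC without WT LT-HSC 1 were added to these. The last was added because that library stood apart. Each count below was compared with the counts from splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included. In LT-HSC 4 of the 100 splits gave as many genes as the real split (1, highest other 4), in MPP 2 of the 100 (5, highest other 5), and in LT-HSC without WT LT-HSC 1 it was 1 of the 100 (203, highest other 29). For MPP versus LT-HSC it was 1 of the 100 in WT (3876, highest other 1770) and 1 of the 100 in Ahr-KO (4041, highest other 1). Each of these 5 shares lay under the limit set in advance. In LT-HSC and MPP another split gave as many genes or more, so that chance is not excluded for these 2 counts. The 203 calls come from the left-out library that gave the most calls, a choice that the splits did not repeat. For MPP versus LT-HSC no other split drawn reached the real count in either genotype. For the difference of the Ahr-KO effect the real count of genes was 0, so that any split gives as many (100 of the 100, highest other 15) and the splits say nothing about chance. The camera p of the Aurora A and G2/M list in MPP was matched by 2 of the 100 splits, the real one included (3.39e-21, smallest other 4.9e-22). Another split thus gave a smaller camera p, so that chance is not excluded for this list. The list was also not called with an estimated correlation (adjusted p = 0.728 with an estimated correlation) or by fry (adjusted p = 0.566).

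The numbers of gene lists called at the preset correlation did not stand out from other splits. In LT-HSC 75 of the 100 splits gave as many lists as the real split (6, highest other 18), in LT-HSC without WT LT-HSC 1 it was 50 of the 100 (10, highest other 19), and in MPP 67 of the 100 (8, highest other 16). For MPP versus LT-HSC it was 9 of the 100 in WT (16, highest other 19) and 20 of the 100 in Ahr-KO (16, highest other 18), and for the difference of the Ahr-KO effect 46 of the 100 (11, highest other 19). Chance cannot be excluded for any of these 6 counts.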
